A study of Mus musculus with 2 samples.

How the data were processed

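Hippocampal RNA of male C57BL/6J mice on a diet with 0.5% astaxanthin powder (ASX) and on a control diet was compared on 2 two-colour Agilent mouse expression arrays. On array 1 (replicate 1) the ASX RNA carried Cy5 and the control RNA Cy3, and on array 2 (replicate 2) the dyes were exchanged. Each array is titled with 4 mice, and the design text names 4 biological replicates per diet; no label says how the RNA of the mice was combined, and each array carried 1 RNA sample per diet. The arrays were therefore treated as a technical dye swap of 1 pair of RNA samples, that is as 1 replicate. Both arrays lay on 1 slide and were scanned together, so no batch separated them.

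Per the file headers and the submitters' processing notes, the arrays were read with Agilent Feature Extraction 11.0.1.1. The deposited intensity of a spot was the median of its pixels in each channel, with a median local background beside it, and neither had been normalized. Per the file headers, the processed intensity had been background-subtracted and dye-normalized (linear and lowess) by the scanner software. The deposited log ratio was log10 of processed Cy5 over processed Cy3, and it was set to 0 where neither channel was significant (4630 features on array 1, 4563 on array 2). The deposited p-value of each log ratio came from the software's error model for single spots, which covers technical error and not the diet. The deposited value table of the whole series was log10 of Cy5 over Cy3 from the same processed signals, with a largest difference of 5e-08 from them, not turned for the dye swap; its medians were 0.0050 and 0.0083. Its scale, centring and direction are thereby known.

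The design fixed before the data were examined named the mean spot signal. The files used here give the median signal in place of it, so the median was used throughout and a comparison of median against mean signal was not run. Background was corrected with limma 3.58.1 in R 4.3.3 by normexp with an offset of 50, and each array was normalized by loess with control spots at weight 0. Control spots (1639 of 45018 features) and spots called non-uniform outliers (3 of the 43379 spots for mouse transcripts on either array) were left out, and no spot was saturated. Ratios were turned to log2(ASX / control), and spots of a probe were averaged. This gave 41174 probes, 245 of them with 10 spots each.

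The files give accessions without gene names. An accession was named through a RefSeq table of assembly GRCm38.p6 by its unversioned form: 23374 probes matched 1 symbol each (16535 symbols), 17800 matched none and 0 matched several. A probe without a symbol kept its accession and was counted as a transcript of its own. No coordinates are given, since the array was designed on another build. A gene took the value of its brightest probe among those well above background for both RNAs on both arrays, a filter that 30078 probes (73.1%) passed.

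With 1 replicate there are no degrees of freedom for a test of the diet, and no p-value across genes is given. A gene was counted as higher or lower when it was at least 1.5-fold apart in the same diet direction on each array. The same rule in the dye direction, which no diet difference can satisfy, gave a reference count. Dye effects enter that count, so it does not estimate how many genes would pass in the diet direction without a diet difference. An SD between the 2 arrays is technical. For 32 gene lists fixed before the data were examined, the median log2 ratio was given with its percentile among 10000 random lists of the same size matched on brightness in 20 bins, as a description of these arrays; a list beyond the 2.5 or 97.5 percentile is called outside the random range. The random lists were drawn from all 23603 genes and transcripts, 10285 of them without a symbol, while list members are genes with a symbol. The median log2 ratio was -0.019 over genes with a symbol and -0.0042 over all, so list percentiles may stand too low. Random lists of genes with a symbol alone were not drawn. Genes well above background for one RNA on both arrays and for the other RNA on neither, over all their probes, were counted apart. They were given as a fold after loess and Aquantile, per channel. The dim RNA was set at the higher of its own signal and the lowest signal among probes well above background. The fold is a lower bound (at least N-fold) where that lowest signal was used. Where the dim RNA's own signal was used, it is the measured ratio and not a bound.

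Genes were named by a rule fixed before the data were examined: the 10 largest and 10 smallest mean log2 ratios among genes that passed, leaving out clone, model and accession names; from each list up to 4 members that passed and, where fewer than 2 passed, those with the largest absolute mean ratio up to 2 named; and up to 4 genes per direction measured for one RNA alone. A gene named outside the rule is said to be, and values of 2 genes that the rule takes are not reported here.

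The steps were tested on simulated data with 30080 probes, real brightness and backgrounds, and 200 probes changed by known folds. Of the seeded probes, 66 of 66 at 3-fold, 58 of 67 at 2-fold and 2 of 67 at 1.5-fold were counted, and 0 of 29880 unchanged probes were. A seeded 2-fold increase came out as a mean log2 ratio of 0.84 in place of 1. An offset shrinks the ratios of dim probes by construction, so ratios below may understate change in dim genes. Recovery was not computed by brightness or with another offset, so the part of the offset in this shortfall was not tested. A simulated list of 15 probes shifted by 0.15 stood at percentile 100.0, and 7 of 100 unshifted lists fell outside the random range. The simulated dye effects and noise were smaller than the real ones: 0 unchanged probes moved with the dye, against 31 genes on the real arrays. The simulated rates and percentiles therefore need not hold for the real data. Alternatives covered the offset, no background subtraction, the scanner's log ratios, median centring, Aquantile, the brightness filter, saturated and outlier spots, the mean over a gene's probes, the deposited value table, each array alone, other thresholds, the mean of the arrays and the scanner's p-value. Computation outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.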

Results

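Gene expression was measured in the hippocampus of male mice that were 11 weeks old and weighed 26 to 28 g at the start. After 1 week of acclimatization the mice received, for 4 weeks, powdered chow with 0.5% (w/w) of a powder holding 2% astaxanthin, a red carotenoid made by the alga Haematococcus pluvialis, or chow with 0% of it and placebo powder. Total RNA of the astaxanthin (ASX) group and of the control group was labelled with different dyes and hybridised together on 2 arrays, with the dyes exchanged between them, and each array is titled with 4 mice. The arrays form 1 replicate of the diet comparison, and their number limits its precision. The ASX RNA was well above background at 77.8% of the 43379 spots for mouse transcripts on array 1 and 76.7% on array 2, and the control RNA at 78.2% and 75.8%. In all, 23603 genes and transcripts, 13318 of them with a gene symbol, were measured for both RNAs on both arrays.

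The comparison asked which hippocampal transcripts differed between mice fed ASX and control mice; the title of the study names adult hippocampal neurogenesis. Few transcripts differed by much. Prl and Gh, which encode the pituitary hormones prolactin and growth hormone, and S100a9 and S100a8, which encode calcium-binding proteins abundant in neutrophils, were higher in the ASX RNA. Trh, the gene of thyrotropin-releasing hormone, Sln, the gene of the calcium-pump inhibitor sarcolipin, and Egr2, an activity-induced transcription factor gene, were lower. Markers of neural stem cells and immature neurons held no gene that passed the size rule in either direction.

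By that rule, 15 genes and transcripts were at least 1.5-fold higher in the ASX RNA on each array and 5 were at least 1.5-fold lower, while 31 were as far apart in the dye direction. Of the 15, 4 had a gene symbol, and of the 5, 4 had one. Prl had a log2 ratio of 1.72 on array 1 and 1.53 on array 2, a mean fold of 3.08. Gh had 1.67 and 0.91, S100a9 1.17 and 1.38, and S100a8 0.63 and 0.67. Trh had -1.28 and -1.10, a mean ratio of 0.438. Sln had -0.93 and -0.92, and Egr2 -0.80 and -0.75. Each of these genes was read by a single probe past the brightness filter; Sln had another that was not well above background for both RNAs. Their SD between the 2 arrays lay between 0.0063 for Sln and 0.53 for Gh on the log2 scale. Prl, Gh, Trh and S100a8 were dim, with mean log2 brightness of 7.44, 7.44, 7.33 and 6.77. The median over RefSeq mRNA probes was 9.76. Their sizes depended on the processing. Over settings with both arrays, spike-in scaling aside, mean log2 ratios ran from 1.46 to 2.72 for Prl and 1.16 to 2.10 for Gh. They ran from 0.54 to 1.61 for S100a8 and -2.1 to -1.07 for Trh. Among transcripts without a symbol, ENSMUST00000101077 was 2.85-fold and AK005009 1.74-fold higher in the mean, and BC110692 had a mean ratio of 0.567. Of the 11 higher transcripts without a symbol, 9 were cDNA clones with AK accessions. No test of the diet was possible with 1 replicate, and the counts depended on scaling: the scanner's own log ratios gave 71 higher and 12 lower (85.5% of them higher, against 75.0%), and centring each array on its median gave 12 and 12 (50%). All the genes named above passed under both of these. Scaling on the spike-in RNAs of the control spots, added after the data were examined, gave 3 higher and 140 lower. Gh and S100a8 did not pass with it.

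**Figure D1:**
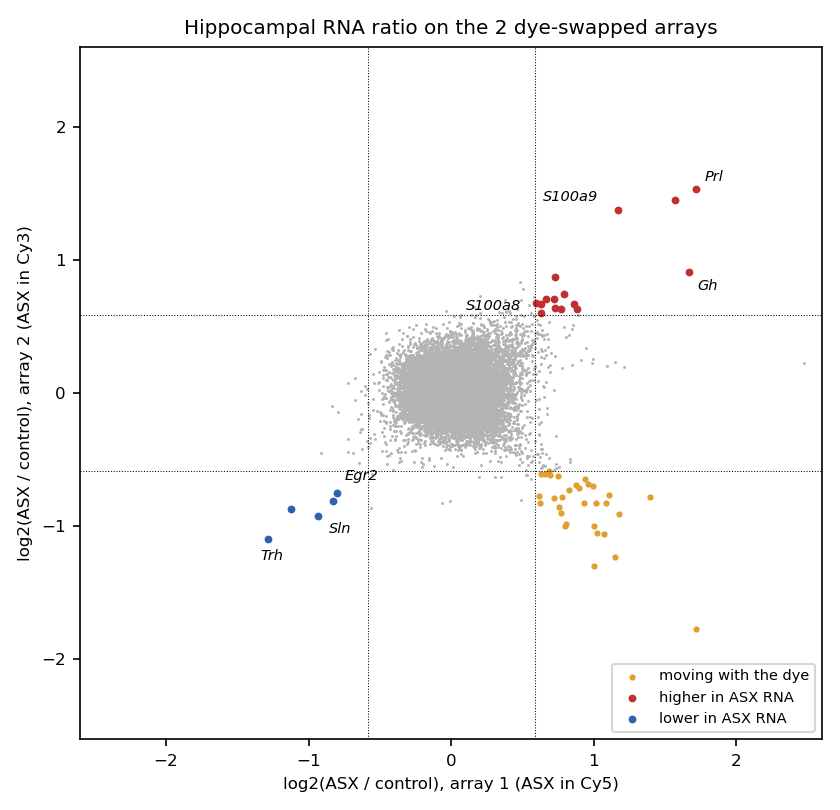
Log2(ASX / control) of 23603 genes and transcripts on array 1 (horizontal) and array 2 (vertical), 1 point each, with dotted lines at 1.5-fold. Red points mark the 15 that were higher on each array, blue points the 5 that were lower and orange points the 31 that moved with the dye; Prl and Gh lie at the upper right and Trh at the lower left.

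Most genes lay close to equal levels: 96.3% were within 1.2-fold in the mean of the arrays. Across genes, which are not independent replicates, the 2 turned arrays had a Pearson correlation of -0.029 and a Spearman correlation of -0.089, so the ratio on one array did not predict that on the other with this scaling; with median centring the correlations were 0.20 and 0.29. Among genes with a symbol the Pearson correlation was -0.25, and among transcripts without one it was 0.13. All 31 genes that moved with the dye were brighter in Cy5 on both arrays, and 17 of them had a mean log2 brightness above 16, as 0.682% of all genes did. A dye effect in 1 direction thus makes up this count, which gives no measure of noise in the diet direction. The 200 measured probes with 10 spots had a median SD over spots of 0.034 for the mean log2 ratio. For 4549 genes with at least 2 measured probes, the diet part of the ratio correlated between the brightest probe and the next at r = 0.43, and had the same sign in 64.5% of genes.

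Lists of the neurogenic lineage had medians slightly below 0. The 14 measured neural stem cell markers had a median log2 ratio of -0.07 (percentile 1.42 among random lists), with Prom1 at -0.22 and Hes5 at -0.16 in the mean; 7 were below 0 on both arrays and 0 above, and the list stood at percentile 1.52 on array 1 and 5.48 on array 2. The 17 markers of neuroblasts and immature neurons had a median of -0.06 (percentile 1.64), with Igfbpl1 at -0.39 and Sox11 at -0.21, but -0.013 on array 1 (percentile 41.65) and -0.07 on array 2 (percentile 4.83), inside the random range on each. Another Sox11 probe past the brightness filter had -0.16 on array 1 and 0.04 on array 2, while other Prom1 and Igfbpl1 probes were below 0 on both. Dcx, the gene of the immature neuron marker doublecortin, singled out after its values were seen, had -0.13 on array 1 and 0.27 on array 2. The 17 cell cycle genes had a median of -0.05 (percentile 4.40), with Ccnb1 at -0.18 and Ccna2 at -0.14, and stood at percentile 44.5 on array 1 and 0.030 on array 2. No member of these 3 lists passed the size rule. With median centring, the stem cell and neuroblast lists stood at percentiles 4.52 and 9.16, inside the random range. The stem cell list was also inside it with the scanner's log ratios (3.70) and without a brightness filter (6.18), and the neuroblast list without a brightness filter (2.66) and with the mean over a gene's probes (7.25).

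Immediate early genes, which neurons transcribe within minutes of activity, had the lowest median outside the lists of neighbouring tissues and ependyma. Their median over 19 measured members was -0.18, -0.16 on array 1 and -0.17 on array 2, and none of the 10000 random lists lay lower. Egr2 was lower by the rule and the other 18 did not pass; Fos had a mean of -0.44 and, singled out after its values were seen, Egr1 had -0.36 and -0.45. In all, 15 of the 19 were below 0 on both arrays, as 23.0% of all genes were, and 0 above. Genes of synaptic plasticity had a median of 0.07 (percentile 99.9, 18 measured), and 0.16 on array 1 and -0.05 on array 2 (percentile 15.8). With median centring, which moves the median of all genes to -0.10, it was -0.16 but stayed outside the random range at percentile 97.53. Grin2a and Grin2b, 2 subunits of the NMDA receptor, had means of 0.47 and 0.24. Nrgn, singled out after its values were seen, moved with the dye, with 1.1 and -0.77.

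Markers of regions and tissues next to the hippocampus differed between the 2 RNAs. The striatal list had a median of -0.19 over 9 measured genes, below all random lists; Penk, the enkephalin precursor gene, had a mean of -0.49, and 8 of 9 were below 0 on both arrays. The thalamic and habenular list had a median of -0.14 (percentile 0.030, 9 measured), with Tnnt1 at -0.46 and Prkcd at -0.32. The 4 measured genes of ependymal cilia, out of 10, had a median of -0.23, below all random lists, with Dynlrb2 at -0.29 and Mia at -0.24. The meningeal list had a median of 0.18 over 14 measured genes, above all random lists; 11 were above 0 on both arrays, none passed the rule, and Bgn and Aldh1a2 had means of 0.28 and 0.25. These 4 lists kept their side and stayed outside the random range under all 11 other settings that used both arrays and were chosen beforehand. Not all of the 11 are separate checks: Aquantile and leaving out saturated spots leave the ratios as they are, and the value table repeats the scanner's log ratios. On array 2 alone the thalamic and ependymal lists stood at percentiles 6.75 and 2.94, inside the random range. Scaling on spike-in RNAs, which moved the median of all genes to -0.38, puts the meningeal median below 0 as well but not its place among random lists. The choroid plexus list had a median of -0.01 (percentile 43.5, 18 measured; 0.03 on array 1 and -0.02 on array 2), with Calml4 at -0.31 and Aqp1 at 0.20, and the neocortical list -0.06 (percentile 4.57, 11 measured), with Foxp2 at -0.49 and Ccn2 at -0.23.

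In the hypothalamic and pituitary list Prl and Gh were higher, Trh was lower and the other 10 of 13 measured genes did not pass; the median was 0.08 (percentile 98.0), 0.20 on array 1 and -0.03 on array 2 (percentile 29.9), and the list lay inside the random range with an offset of 16 (percentile 95.55), with median centring (97.2) and with genes above background for at least 1 RNA (97.2). The wider list of hormones and hormone receptors had a median of 0.02 (percentile 79.1), with Prl and Gh its 2 members that passed of 14 measured; its median was below 0 with the scanner's log ratios and with median centring. In the blood list S100a8 and S100a9 were higher, and the other 4 of 6 measured genes did not pass. The haemoglobin genes Hba-a1 and Hbb-bt, singled out after their values were seen, had means of -0.46 and -0.53, so the list's median of -0.13 (percentile 0.130) and its mean of 0.11 differ in sign. The median was 0.01 without a brightness filter, and the list stood at percentile 10.9 on array 1, inside the random range, and 0.250 on array 2.

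**Figure D2:**
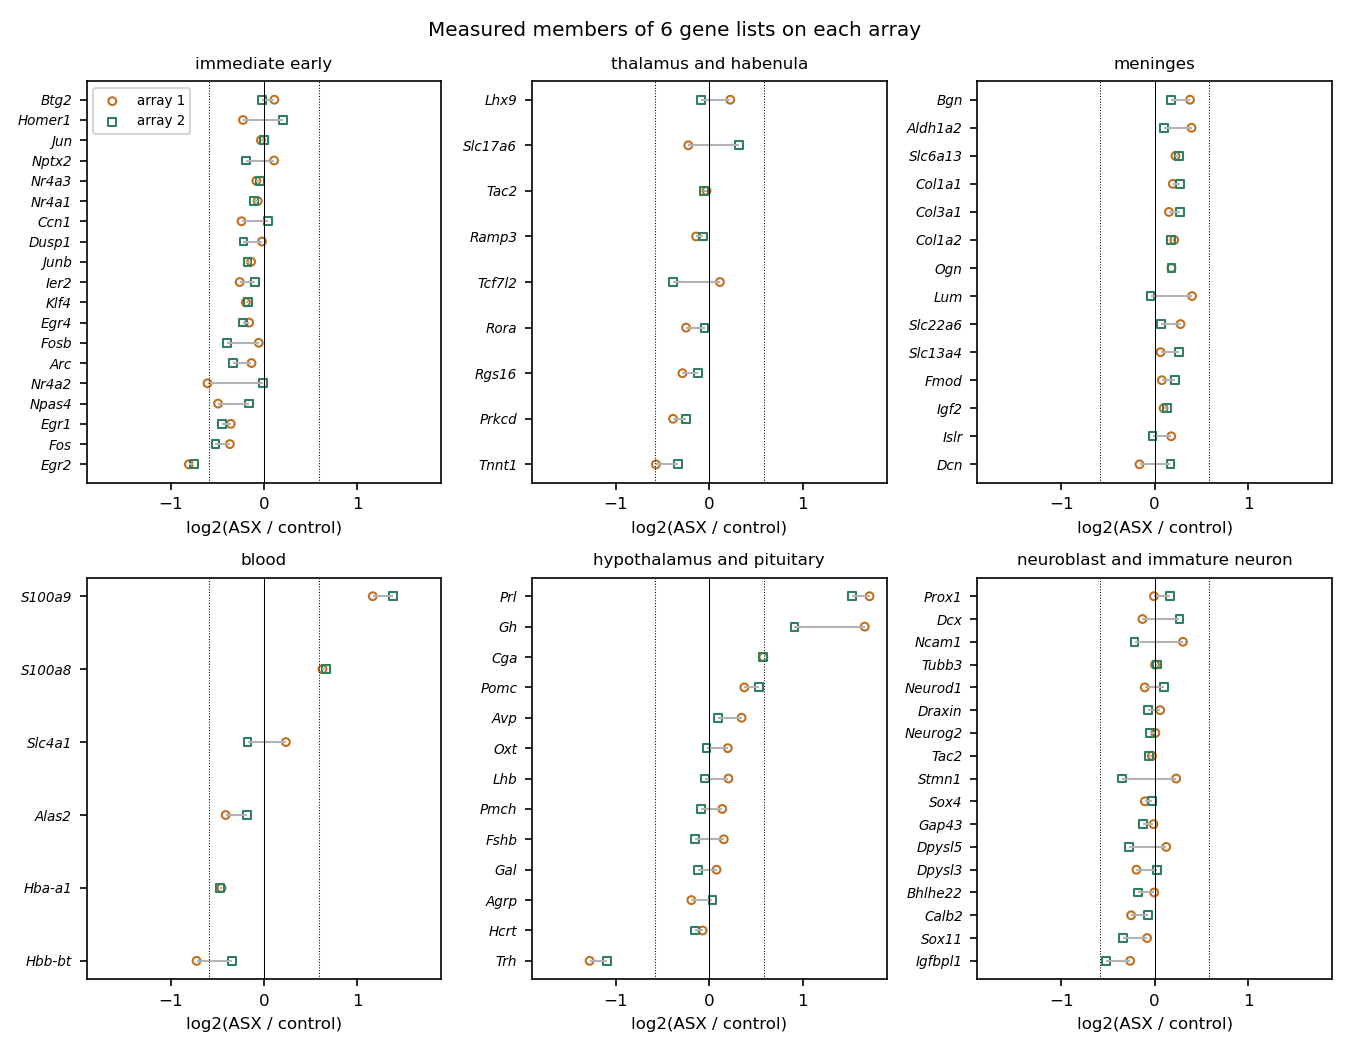
Log2(ASX / control) of each measured member of 6 gene lists (horizontal axis) on array 1 (circles) and array 2 (squares), with dotted lines at 1.5-fold. Prl, Gh, S100a8 and S100a9 lie beyond the line on the right on both arrays, and Egr2 and Trh beyond that on the left.

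Lists drawn up for the supplement itself moved little, and none of their members passed the rule. The 25 antioxidant genes and Nrf2 targets had a median of -0.04 (percentile 1.56), with Mt2 at 0.25, from 0.62 and -0.12 on the arrays, and Gsta4 at -0.15. Genes of retinoid and carotenoid handling had a median of -0.08 (percentile 0.120, 14 measured), with Rxrg at -0.26 and Aldh1a2 at 0.25. With median centring these 2 lists stood at percentiles 6.06 and 18.3. On the single arrays the antioxidant list stood at percentiles 28.7 and 11.7, inside the random range on each, and the retinoid list at 11.8 on array 1 and 2.34 on array 2. Inflammation genes had a median of -0.06 (percentile 5.97, 10 measured), with Ccl3 at -0.26 and Cxcl10 at 0.25. Apoptosis genes had -0.05 (percentile 3.24, 17 measured), with Xiap at 0.24 and Bcl2 at -0.20. Another Bcl2 probe past the brightness filter was above 0 on both arrays, at 0.04 and 0.17. PPAR and lipid genes had 0.01 (percentile 72.7, 19 measured), with Plin2 at -0.18. The PPAR and lipid median was 0.08 on array 1 and -0.07 on array 2. It was below 0 with the scanner's log ratios and with median centring. Growth factors and their receptors had -0.02 (percentile 25.95, 18 measured), with Igf1r at 0.23 and Hbegf at -0.22. Other Igf1r probes past the brightness filter had means of 0.06 and 0.02. Genes of Wnt, BMP, Notch and hedgehog signalling had -0.02 (percentile 23.2, 23 measured), with Ptch1 at -0.30 and Wnt7a at -0.24; this list stood at percentile 54.3 on array 1 and 1.28 on array 2.

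Glucocorticoid response genes had a median of 0.07 (percentile 98.5, 11 measured), which was -0.06 on array 1 and 0.08 on array 2, inside the random range on each, and -0.13 with median centring (percentile 92.75); the list was also inside that range with the scanner's log ratios (95.4) and with the mean over a gene's probes (96.8); Cdkn1a, the gene of the cell cycle inhibitor p21, had -0.55 and -0.61, and Pdk4 a mean of -0.17. The mean over the glucocorticoid list was -0.03, opposite in sign to its median. Circadian clock genes had a median of -0.01 (percentile 36.9, 15 measured), with Per3 at 0.27 and Dbp at 0.22, but medians above 0 on each array, 0.05 and 0.06, and above 0 with the mean over a gene's probes. No member of the lists of hippocampal neurons and glia passed the rule. Medians of the neuronal types were 0.06 for mature dentate granule cells (percentile 95.9), with Stxbp6 and Tdo2 at 0.13 each, 0.04 for CA1 pyramidal cells (percentile 88.7), with Ndst4 at 0.13 and Ccn3 at -0.09, and -0.01 for CA2 and CA3 pyramidal cells (percentile 44.4), with Cacng5 at -0.19 and Iyd at -0.12, but 0.02 on array 1 and -0.03 on array 2; with median centring the granule and CA1 medians were -0.06 and -0.14, at percentiles 96.95 and 80.2. Interneuron genes had -0.07 (percentile 0.220), with Tac1 at -0.24 and Calb2 at -0.16, but 0.06 on array 1 and -0.14 on array 2. Among glia and vessels, mature oligodendrocytes had a median of -0.06 (percentile 0.530, but 9.82 and 13.5 on the single arrays, inside the random range on each; Klk6 -0.17, Mobp -0.12), their precursors -0.05 (percentile 8.52, 0.040 on array 1 and 41.4 on array 2; Cspg4 -0.27, Gpr17 -0.25), astrocytes -0.03 (percentile 17.2, but 97.1 on array 1 with a median of 0.11 and 1.42 on array 2 with -0.11; Slc1a2 0.22, S100b -0.12), microglia -0.03 (percentile 15.7; Tmem119 -0.17, P2ry12 -0.12) and endothelial cells and pericytes -0.03 (percentile 14.7, but medians above 0 on each array, 0.07 and 0.03; Pdgfrb 0.23, Cldn5 -0.20). The arrays had opposite signs for Cacng5, Iyd and Mobp, above 0 on array 1 alone, and for S100b and Cldn5, above 0 on array 2 alone. Another Mobp probe past the brightness filter had 0.07 on array 1 and -0.06 on array 2, and another Slc1a2 probe 0.28 and -0.04. Other Calb2 probes were below 0 on both arrays.

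Of the 32 lists, 15 lay outside the random range, 11 below and 4 above it, and 11 of the 15 had medians on the same side of 0 on both arrays. With median centring, 8 lists lay outside and 6 of the 15 were among them on the same side; on array 1 alone 8 of the 15 stayed outside, and on array 2 alone 6. Under all settings with both arrays chosen beforehand, 6 of the 15 stayed outside, namely the immediate early, synaptic plasticity, striatal, thalamic, ependymal and meningeal lists, and the other 9 were inside under at least 1. Not all of these settings are separate checks, as said above for the lists of neighbouring tissues. Some lists share members, and genes that move together were not modelled in the random lists. The random lists also held transcripts without a symbol, whose ratios ran higher than those of genes with one. List percentiles may therefore stand too low, which matters most for medians close to 0.

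**Figure D3:**
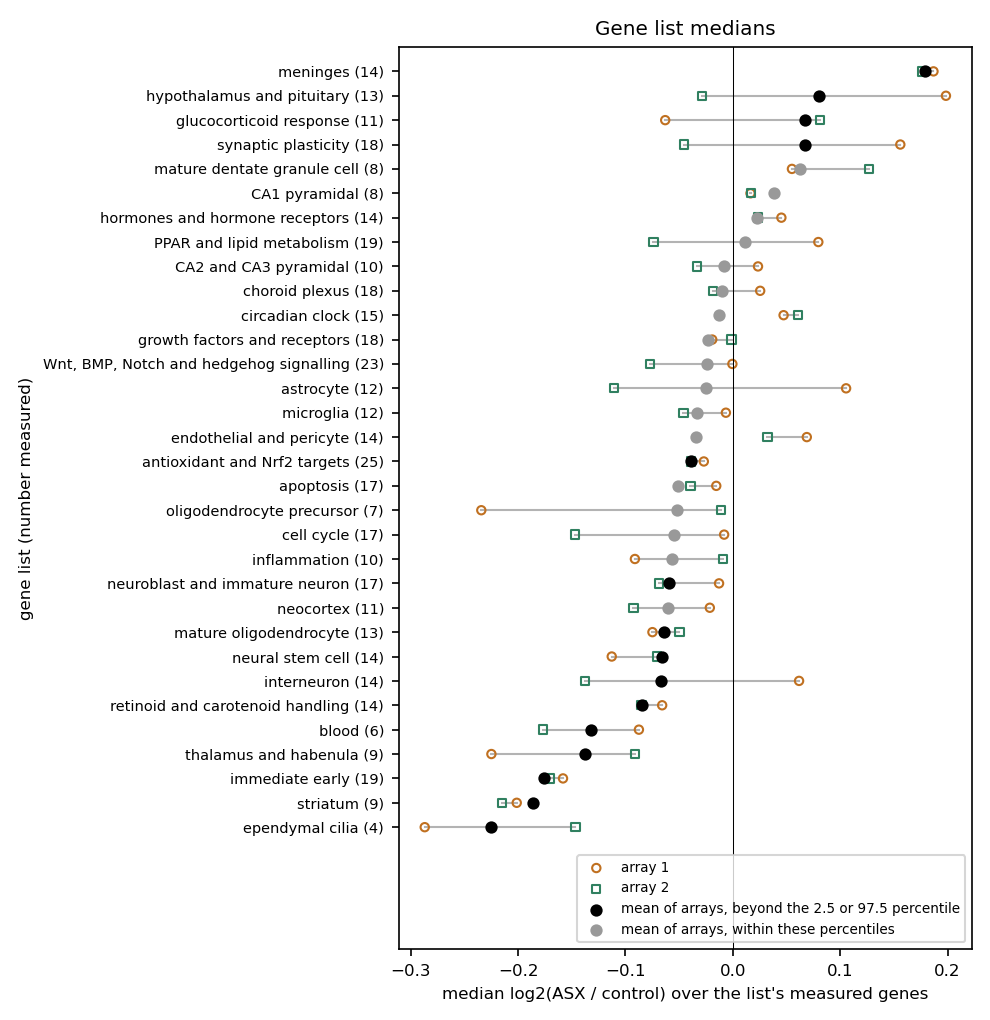
Median log2(ASX / control) of each of the 32 gene lists (horizontal axis) on array 1 (open circles), on array 2 (open squares) and for the mean of both (filled circles, black where outside the random range); the number of measured members follows each name. Meninges stand highest at 0.18 and ependymal cilia lowest at -0.23; the synaptic plasticity and glucocorticoid medians, above 0 here, fall below 0 with median centring, as does the median of all genes.

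A further 81 genes and transcripts were well above background for one RNA alone, 53 for the ASX RNA and 28 for the control RNA. Of them, 0 had a bound or ratio of 1.5-fold or more. The clone AK076708, counted on the ASX side, had a ratio of 0.95, which is the other way. Among the 7 with a symbol on the ASX side, Gja6 and Ltf had a measured ratio of 1.2-fold, Acsm3 of 1.08-fold and Xlr5a of 1.07-fold. These are ratios to a control signal that was not well above background, and not lower bounds. Among the 12 on the control side, the control RNA exceeded the ASX RNA at least 1.36-fold for Lhx8. The measured ratios, again not bounds, were 1.17-fold for Isl1, 1.17-fold for Chdh and 1.16-fold for Vax1. Lhx8, Isl1 and Vax1 encode transcription factors of the developing ventral forebrain.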

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

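The comparison by brightness below was set down before its result was seen; the tests by array and of the spike-in level were chosen after.

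The spike-in RNAs, which lie on control spots outside the comparison, read higher for the ASX RNA in the mean of the 2 turned arrays. On the single arrays their log2 Cy5 over Cy3 ratios, each from 32 spots, ran from -3.11 to 3.24. Of the 10 spike-ins, 2 read higher in the channel of the ASX RNA on both arrays. Each of the others had the same sign of Cy5 over Cy3 on both arrays. A part that stayed with the dye set that sign, so it does not tell the 2 RNAs apart. The labels do not say how much of each spike-in was added with each dye. Whether that part came from the dyes or from different added amounts is therefore not known. In the mean of the turned arrays, in which a part that follows the dye cancels, all 10 were above 0: their mean log2(ASX / control) was 0.37 with an SD of 0.042 over spike-ins, from 0.27 to 0.41, a mean fold of 1.29. The scanner's own ratios gave a mean of 0.38. All 10 were read on the same labelled RNAs, so they are not 10 separate measures of a difference between the RNAs. The SD over spike-ins is agreement among them. An unequal amount added at a labelling could shift all of them together and would not cancel in the turned mean. There were no control samples beyond the 2 RNAs themselves. Scaling was on the mouse transcripts. A value of 0 therefore needs, for each dye, equal amounts of spike-in added to both RNAs, and an equal share of mRNA in both.

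A second pattern goes in the same direction: probes from cDNA clones with AK accessions had a median log2 ratio of 0.039, against -0.017 for probes of RefSeq mRNAs, and 95 of 6156 clone probes were at least 1.3-fold higher on each array. Brightness is argued against as the source, since the difference of 0.056 was 0.063 (SD 0.0014 over 1000 draws) when RefSeq probes were drawn to match the clones on brightness, and the matched draws held a mean of 6.23 probes at 1.3-fold. A dye effect is also argued against, since the smaller of the differences on the 2 arrays, which carry opposite dyes, was 0.061. A lower share of spliced mRNA in the ASX RNA could give both the spike-in level of 0.37 and the higher clone probes. Unequal amounts of added spike-in could give the first but not the second, since control spots had no weight in the scaling. Which clones come from unspliced RNA was not tested without a genome, and 1 RNA per diet leaves RNA quality and diet confounded.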

How the results depend on the processing

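All settings except spike-in scaling and the count over genes with a symbol were chosen before the data were examined; these 2 were added after. No setting turned the sign of any of the 20 transcripts that passed, but many settings could not. Other thresholds and rules, the single arrays and the count over genes with a symbol reuse the same values, so the signs were fixed there. On single arrays, at 1.3-fold, at 0.75-fold, in the mean and among genes with a symbol, passing was fixed as well. The genes named in the report as higher or lower passed under every setting except no background subtraction (S100a8 lost), 2-fold (Gh, S100a8, Sln and Egr2 lost) and spike-in scaling (Gh and S100a8 lost). The cause of the changes below was not tested, except that another threshold or rule, fewer genes or a common shift changes counts by construction.

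Higher genes numbered 15 in the report, 28 with an offset of 16, 71 with the scanner's log ratios or the deposited value table, 3 at 2-fold, 116 at 1.3-fold, 34 at 1.5-fold in the mean of the arrays, 72 by the scanner's p, 3 with spike-in scaling and 4 among genes with a symbol. Lower genes numbered 5, but 12 with the scanner's log ratios, the value table or median centring, 1 at 2-fold, 22 at 1.3-fold, 18 at 0.75-fold, 8 in the mean, 13 by the scanner's p and 140 with spike-in scaling. Genes moving with the dye numbered 31, but 79 with the scanner's log ratios or the value table, 73 with median centring, 47 without a brightness filter, 4 at 2-fold, 97 at 1.3-fold, 12 with spike-in scaling and 18 among genes with a symbol. Single arrays gave 36 to 137 higher and 28 to 47 lower genes. Spike-in scaling moved the median of all genes from -0.0042 to -0.38 and median centring to -0.10; the first is a common shift that leaves list percentiles as they were.

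The correlation of the arrays, -0.029, was -0.0051 with an offset of 16, -0.045 without background subtraction and -0.14 without a brightness filter; it was above 0 with the scanner's log ratios and the value table (0.013), the mean over probes (0.021) and median centring (0.20). Lists outside the random range numbered 15, 8 with median centring and 9 to 10 on single arrays, where 6 to 8 of the 15 stayed. Of these 15, the synaptic plasticity median became -0.16 (still outside, at percentile 97.53) and the glucocorticoid median -0.13 with median centring, and the blood median 0.012 without a brightness filter. On single arrays the medians ran from -0.046 to 0.16 for synaptic plasticity, -0.063 to 0.081 for glucocorticoid response, -0.029 to 0.20 for the hypothalamus and pituitary and -0.14 to 0.062 for interneurons. Single arrays turned the sign of 10 of the 32 list medians, 2 of them on both arrays, and of 6 of 63 named genes. Under the other settings, list medians that kept their sign or lay inside the random range moved by more than the SD between the arrays in 57 cases and by less in 228, and named genes in 91 and 476; the sign turned in 13 cases for list medians and 3 for named genes. Leaving out saturated spots removed nothing and Aquantile leaves ratios as they are, so neither tests anything. Median against mean signal was not run, for lack of the mean in the files used here. No paired analysis was possible because the result comes from no test and both arrays are of 1 group. Signal over background limits the comparison to 73.1% of probes.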

Other observations

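The second lists of striatal, thalamic and meningeal markers were set down before their results were seen; the test on Prl and Gh was chosen after.

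At 1.3-fold on each array, 22 genes and transcripts were lower and 116 higher, of which 15 and 7 had a gene name. Beyond those already named, the lower ones included Zic1, a transcription factor gene, at a mean log2 ratio of -0.71, Stk32c, a kinase gene, at -0.68, Slc10a4, a transporter gene of cholinergic and monoaminergic neurons, at -0.59, Ido1, an enzyme of tryptophan breakdown, at -0.57, and Islr2 at -0.45. The higher ones included Cga, the alpha subunit shared by pituitary glycoprotein hormones, at 0.58, and Kcnj3, a gene of a G protein-gated potassium channel, at 0.42. These genes were singled out after their values were seen, and no replicate of the diet bears on them.

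A candidate explanation for the lists of neighbouring tissue is that the dissected pieces held unequal amounts of it. A second list of 18 striatal markers that shares no gene with the first had a median of -0.13 over 15 measured members, at percentile 0.0 of random lists (3.78 on array 1 and 0.720 on array 2), with Ido1 at -0.57 and Slc35d3 at -0.43, while abundant Pdyn stood at 0.04. A second meningeal list had a median of 0.055 over 18 of 19 members, at percentile 98.2 (74.8 on array 1 and 99.1 on array 2), less than the 0.18 of the first list. Its bright members Mgp and Vtn had 0.12 and 0.11, while Thbs2 and Col6a1 stood at -0.17 and -0.15. On both arrays, 7 of its members were above 0 and 2 below. The 2 second lists go with less striatal and more meningeal tissue in the ASX RNA, though the hippocampal RNA expressed most of these genes above background. A second thalamic list had a median of -0.022 at percentile 38.2 (23.8 on array 1 and 73.1 on array 2), which argues against less thalamic tissue as the source of the first thalamic median of -0.14, as far as the 6 measured members of 12 go; that median stays open. An effect of the diet on these genes within the hippocampus stays open, untested, since each diet is represented by 1 RNA.

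Prl and Gh were the pair of hormone genes furthest above 0. Pituitary tissue in the ASX RNA may account for them: it would bring other abundant hormone transcripts, and Pomc and Cga had log2 ratios of at least 0.38 on each array. Fshb and Lhb had means of 0.00012 and 0.080, Tshb was not well above background, and a list of other pituitary markers had a median of -0.043 at percentile 12.6 with 8 of 17 members measured, and did not rise with them. Expression of these hormones in the hippocampus itself under the diet stays open and untested.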
